A study of Mus musculus with 127 samples.

How the data were processed

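Poly(A) RNA-seq libraries were made from whole cortex and from cell fractions of cortex of germline and conditional Chd8 mutant mice. Fractions were separated with commercial synaptosome and nuclear extraction reagents, per the labels' protocols, which also give RIN scores for the whole tissue RNA and paired-end sequencing. Of 127 labelled libraries 123 were analysed, and 4 cytosolic libraries were not analysed here. The authors deposited tables of raw counts per gene, of which 5 were used. Reads were aligned with STAR 2.5.4b to GRCm38 and counted with featureCounts 2.0.0, per the submitters' processing notes. Per the file headers, conditional cortex was counted with featureCounts 1.6.0 on Ensembl annotation 95, with no strand option, so antisense and overlapping genes cannot be told apart there. The same header holds no option for read pairs although sequencing was paired-end. In all experiments even counts were more frequent than odd ones (56.3 to 74.7% of counts from 10 to 200 per library) and every Cre count was even, so mates appear to have been counted separately for many genes. Totals and Cre values are therefore taken as reads rather than fragments, whose number may be as low as 50% of them. For the other tables the strand setting is not given in the sources used here. Reads from processed copies of a gene may be lost or shared, which bears most on ribosomal protein genes.

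The tables share 54838 gene rows, of which 54723 IDs matched a symbol and 115 did not. A Cre row held at most 0.00135% of the reads of a library and was left out of totals and tests. In all, 16 libraries appeared in 2 tables with identical counts and were used once. Within groups, no 2 libraries agreed within sampling noise (lowest chi-square per degree of freedom 4.66). Groups came from sample titles and characteristics, with genotype and sex as labelled. Each library is described as a separate animal within a fraction, and nuclear and synaptic libraries with the same animal number were taken as 1 animal. In 1 of the 10 germline WT pairs the nuclear library (WT male replicate 7) has female and the synaptic library (WT male replicate 6) male sex markers, so these 2 cannot come from 1 animal. The conditional animal labelled HET in its nuclear library (HET female replicate 4) and HOM in its synaptic library (HOM female replicate 2) was left out of the interaction fit.

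Each comparison was tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on the deposited counts, with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. Covariates were sex and batch (2 labels) in germline cortex, sex and 3 groups of batch labels in germline nuclear and synaptic libraries, and sex elsewhere, since the other experiments have 1 batch label. Synaptic and nuclear libraries were compared with animal as a block. The pairing comes from animal numbers in the library names (10 WT and 5 HET germline animals, and 4 WT, 5 HET and 3 HOM conditional animals). Standard errors were computed from the fold change and its F statistic. CPM values are counts per mega count (M) of the deposited gene counts, and levels set across tables were not normalised together. For conditional cortex the protocol counts 6 WT and 8 heterozygous floxed animals. The titles give heterozygous floxed animals with and without Cre, and the titles were followed. Because Cre and deletion go together in conditional cortex, their effects cannot be told apart there.

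Gene lists (35) of cell types, brain regions, synaptic and housekeeping functions and RNA classes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, for lists with at least 5 tested members. Fold changes of cortex were compared with those of the other data sets by Pearson correlation, with a reference from up to 100 splits of the second data set. Named genes followed a rule: Chd8; among genes with an adjusted p under 0.05, an average log2 CPM of at least 1 and an ordinary symbol, the 8 largest changes each way; the 2 members with the smallest p of each called list; and, between compartments, the 5 largest each way and the members of the nuclear-retained and dendritic lists. Usp11, Crlf2, Dsn1, Abca8a, Xist and Ddx3y were named in further places after their values were seen. Single genes were tested with exact permutation tests, or with 100000 resamples where both groups had at least 10 libraries, all two-sided. For differences of Chd8 between fractions per pair, each fraction was scaled by itself with TMM, while the fits between compartments scaled both together. Coordinates and overlapping genes were taken from GENCODE release M21 with bedtools 2.31.1, and figures were drawn with matplotlib 3.10.9.

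The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, voom with sample weights, a replicate block, other covariates, single batches, and each library left out in turn. Chosen after seeing the data were fits without 2 synaptic libraries of nuclear profile, without 2 nuclear libraries whose sex markers go against their label, and without the conditional animal with 0 Cre reads (HET male replicate 1 in both fractions). So were the fits without the WT pair that disagrees in sex markers and the exact tests of Chd8 and Usp11 with genotype permuted within sex and batch group. Splits of the samples permuted genotype within sex and batch group. Their statistic was the number of calls or, where that was 0, the number of genes at an unadjusted p under 0.05, which was decided after the 0 was seen.

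The code was tested on simulated data with 200 changed genes drawn at the means and library sizes of each comparison. In germline cortex (17074 genes) it recovered 78 of 100 genes changed by a log2 of 0.5 and 99 of 100 changed by 1, with 11 false calls, and in the nuclear fraction (19912 genes) 17 and 91 of 100, with 8 false calls. In the synaptic fraction (17178 genes) it recovered 3 and 71 of 100, and in HOM conditional nuclei (21133 genes) 0 and 25 of 100. For both compartment interactions a first run at the sizes of 0.5 and 1 recovered none, and the sizes were then raised to 1 and 2.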

Results

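RNA was measured by poly(A) RNA-seq in the cortex of mice aged about 60 days that carried mutations of Chd8, a chromatin remodeller gene in which loss-of-function mutations are associated with autism. The germline line carried 1 mutant allele, which the protocol names as a 5 bp deletion, and its heterozygotes (HET) were compared with wild-type (WT) mice. In the conditional line a floxed allele was removed by Camk2a-Cre, which acts in excitatory forebrain neurons. The stated purpose was to describe expression in whole cortex and in cell compartments of the adult mutants. Whole cortex of the germline line gave 31 libraries (15 WT and 16 HET). Its nuclear fraction gave 21 libraries (12 WT and 9 HET), its synaptic fraction 18 (11 WT and 7 HET) and its cytosolic fraction 12 (5 WT and 7 HET). By its titles, conditional cortex comprised 8 heterozygous floxed (Chd8+/flox) libraries without Cre and 6 with Cre. The protocol text describes WT and floxed groups, so what the contrast compares is in doubt beyond the presence of Cre reads. Conditional nuclear libraries numbered 13 (4 WT, 6 HET and 3 homozygous, HOM) and synaptic libraries 14 (4 WT, 5 HET and 5 HOM).

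Depth differed between experiments. Total gene counts per library, in mega counts (M), ranged from 19 to 30.5 M in germline cortex, from 23.2 to 50.7 M in the germline nuclear fraction, from 26.6 to 48.0 M in the synaptic fraction and from 33.0 to 56.6 M in the cytosolic fraction. Conditional cortex was the deepest, at 98.1 to 134.6 M, against 24.4 to 53.8 M in conditional nuclear and 31 to 56.2 M in conditional synaptic libraries.

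Chd8 (ENSMUSG00000053754) lies on the minus strand of chromosome 14, from 52198151 to 52257780 in GRCm38. An antisense gene, Gm26590, overlaps at least 1 of its exons, and the counts may not separate the strands. In germline cortex Chd8 fell from 93.2 ± 13.8 CPM in WT (SD, n = 15) to 62 ± 11.9 CPM in HET (SD, n = 16), or 67% of the WT level in the model (log2 fold change −0.58, SE 0.0751, edgeR adjusted p = 6.18e-05). The permutation p of 1e-05 was the smallest that the resampling can give. Within the batches the log2 difference was −0.57 (15 libraries, exact permutation p = 0.000777) and −0.60 (16 libraries, exact permutation p = 0.000155).

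The fractions of the germline line differed in their Chd8 levels. In the nuclear fraction Chd8 was at 117 ± 10.7 CPM in WT (SD, n = 12) and 117 ± 17 CPM in HET (SD, n = 9), with a log2 fold change of −0.01 (95% interval −0.14 to 0.11; exact permutation p = 0.973). In the synaptic fraction it was at 69.9 ± 38.5 CPM in WT (SD, n = 11) and 33.5 ± 4.06 CPM in HET (SD, n = 7; log2 fold change −0.82, SE 0.192, exact permutation p = 0.000786). Genotype and batch are unevenly spread in that fraction: with 6 batch levels the fold change was −0.40 (edgeR adjusted p = 0.421). Within sex and batch group, where 3 HET and 5 WT libraries can be compared, the difference was −0.61, with an exact permutation p of 0.0333 that is the smallest possible. Both WT males of replicates 1 and 2 in that fraction had a nuclear profile. Without them Chd8 stood at 53.1 ± 10 CPM in WT (SD, n = 9) and the log2 fold change was −0.67 (SE 0.0741, edgeR adjusted p = 6.26e-05), or −0.61 with 6 batch levels (adjusted p = 0.0225). It kept its size but did not pass with genotype alone (−0.65, adjusted p = 0.0725) or the replicate block (−0.64, adjusted p = 0.519). In the cytosolic fraction Chd8 was at 86.4 ± 5.07 CPM in WT (SD, n = 5) and 64.5 ± 7.31 CPM in HET (SD, n = 7), and the log2 fold change of −0.43 (SE 0.0835) had an exact permutation p of 0.00126. All HET libraries of that fraction lay below all of its WT libraries, at 55.5 to 77.1 CPM against 77.6 to 90.1 CPM. Over all genes the synaptic and cytosolic values did not pass in edgeR (adjusted p = 0.316 and 1).

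In the conditional line the largest Chd8 differences were those of Cre in cortex and of HOM. Cre-positive cortex had 51.7 ± 11.3 CPM (SD, n = 6) and Cre-negative cortex 73.4 ± 18.9 CPM (SD, n = 8), a log2 fold change of −0.52 (SE 0.197, exact permutation p = 0.039). HOM against WT gave −0.57 in the synaptic fraction (SE 0.196, n = 5 and 4, exact permutation p = 0.0476) and −0.47 in the nuclear fraction (SE 0.161, n = 3 and 4, exact permutation p = 0.0571). Without the animal labelled HET in its nuclear and HOM in its synaptic library, the synaptic difference was −0.63 (n = 4 and 4, exact permutation p = 0.0571). Without HOM female replicate 1 the nuclear value was −0.20, and without HOM male replicate 2 it was −0.65. HET against WT gave −0.21 in the synaptic fraction (n = 5 and 4, exact permutation p = 0.198) and −0.06 in the nuclear fraction (n = 6 and 4, exact permutation p = 0.41). By the titles these HET libraries and Cre-positive cortex have the same genotype, and the difference between their values was not tested. After Benjamini-Hochberg adjustment over the 15 tests of Chd8, the exact p of the conditional cortex and HOM comparisons was 0.0779 each.

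**Figure D1:**
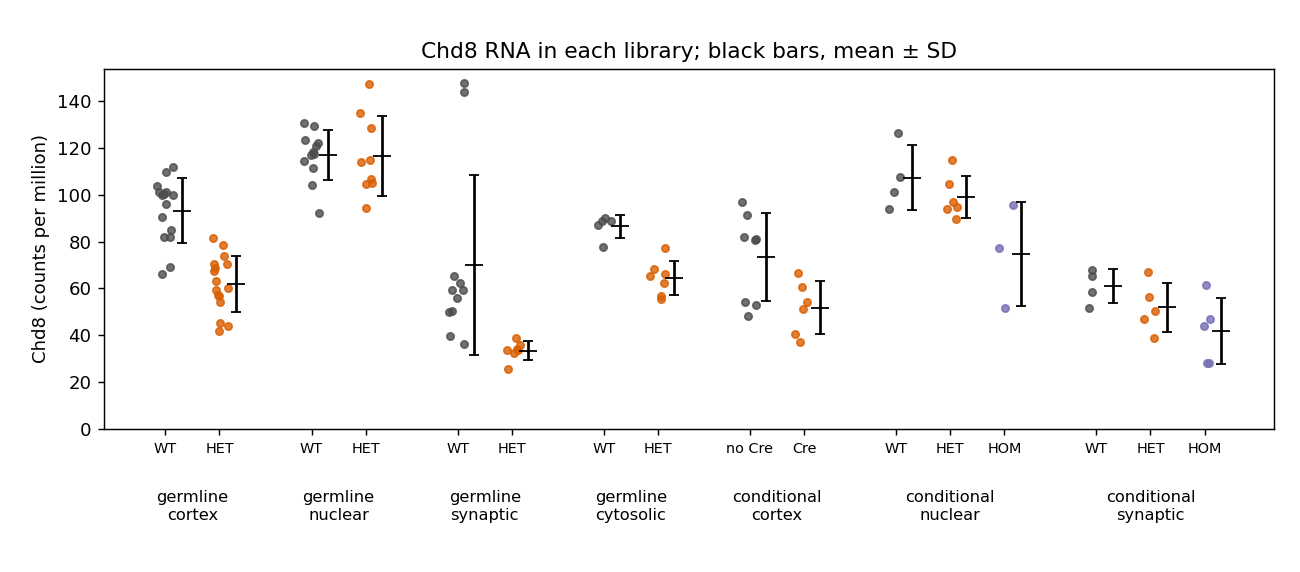
Chd8 in CPM (y axis) in each library (points), by experiment and genotype (x axis); black bars give the mean ± SD of each group. HET libraries of germline cortex lie between 41.7 and 81.3 CPM and WT libraries between 65.9 and 112 CPM, while in the germline nuclear fraction both genotypes average 117 CPM, and 2 WT synaptic libraries stand above all others of their fraction.

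Whole cortex of germline HET mice was compared with WT to find genes that respond to loss of 1 Chd8 allele. Of 17074 genes tested, 32 rose and 24 fell in edgeR at an adjusted p under 0.05. Usp11, an X-linked deubiquitinase gene, had the smallest p: it fell from 138 ± 13 to 105 ± 12.8 CPM (SD, n = 15 and 16; log2 fold change −0.38, SE 0.05, adjusted p = 6.18e-05). The meiotic cohesin gene Rec8 fell (−0.66, SE 0.13, adjusted p = 0.0177), as did the transporter gene Abca8a (−0.60, SE 0.09, adjusted p = 0.0003), the kinetochore gene Dsn1 (−0.47, SE 0.10, adjusted p = 0.0265), the tight junction gene Cgn (−0.47, SE 0.11, adjusted p = 0.0492), Megf6 (−0.54, SE 0.13, adjusted p = 0.0495) and Ddo, which encodes D-aspartate oxidase (−0.44, SE 0.10, adjusted p = 0.0471). Egfl6, a secreted factor, had the largest named increase, from 2.86 ± 0.543 to 4.77 ± 1.24 CPM (SD; log2 fold change 0.70, SE 0.11, adjusted p = 0.000432). Also higher were the cytokine receptor gene Crlf2 (0.42), the ADP-ribose hydrolase gene Oard1 (0.40), the mitochondrial tRNA synthetase gene Wars2 (0.36), the sulfurtransferase gene Mpst (0.33), and Zfp438, Dnajc4 and Rmdn2 (0.32 each), with SEs of 0.05 to 0.07 and adjusted p of 0.0003 to 0.0323. Of the 17 genes named by the rule, 1 has an antisense partner, which is Chd8.

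Fixed gene lists added small, broad differences in germline cortex. Camera called 8 of 35 lists with its preset correlation. Nuclear-encoded oxidative phosphorylation genes lay above 0 in 75 of 79 members (median log2 fold change 0.08), with 0 members passing when adjusted over the list alone and 0 over all genes (adjusted p = 0.86 with an estimated correlation). Meningeal fibroblast and collagen genes had a median of 0.20, with 3 of 19 higher when adjusted over the list alone and 0 over all genes (adjusted p = 0.85 with an estimated correlation). Choroid plexus and ependyma genes had a median of −0.49, and 6 of 13 were lower when adjusted over the list alone. The water channel gene Aqp1 was the 1 member that passed over all genes (−1.93, SE 0.37, adjusted p = 0.00961), and the list had an adjusted p = 0.85 with an estimated correlation. The mean log2 CPM of that list was 0.09 ± 0.37 in HET and 0.69 ± 0.87 in WT (SD, n = 16 and 15, permutation p = 0.0157), so the libraries differed in choroid plexus markers as well as in genotype. Nuclear-retained RNAs had a median of −0.30, with 1 of 16 lower adjusted over the list alone (adjusted p = 0.85 with an estimated correlation). Splicing genes (65 of 90 below 0) and chromatin remodelling genes (64 of 78 below 0) had medians of −0.06 and −0.05, and 16 of 16 astrocyte markers lay above 0 (median 0.10), each with 0 members passing adjusted over the list alone and an adjusted p = 0.86 with an estimated correlation. Neuropeptides had 19 of 24 above 0 (median 0.07, 0 adjusted over the list alone, adjusted p = 0.88 with an estimated correlation).

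Of the 56 genes called in germline cortex, 54 had the same direction in both batches. They were chosen from these same libraries, so that count says little by itself. Batch CHD80456 alone called 0 genes in edgeR (624 at an unadjusted p under 0.05) and batch CHD807 alone called 1 (2043 at an unadjusted p under 0.05). Removing 1 library lowered the 56 calls by more than 1.5 times in 7 cases: to 29 without HET male replicate 3 or WT female replicate 2, 31 without WT female replicate 4, 35 without HET female replicate 3, 36 without WT male replicate 6, and 37 without HET female replicate 1 or HET male replicate 7. RLE scaling called 24 higher and 25 lower, against 32 and 24 with TMM.

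Sex was tested as a modifier of the genotype effect in the same 31 libraries. The Chd8 effect was −0.60 in females (SE 0.106) and −0.55 in males (SE 0.11), with an interaction of 0.05 (SE 0.153, edgeR adjusted p = 1). The interaction called 0 genes in edgeR and 0 in DESeq2, with 261 genes at an unadjusted p under 0.05 where 854 are expected by chance. Females alone gave 1 higher and 5 lower gene, and males 1 higher and 0 lower.

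The nuclear fraction asks which genes differ at the level of nuclear RNA. Ryr1, a ryanodine receptor gene, rose from 49.7 ± 8.49 CPM in WT to 69.1 ± 6.83 CPM in HET (SD, n = 12 and 9; log2 fold change 0.51, SE 0.08, edgeR adjusted p = 0.0182), and annotation places 2 antisense genes on it. Tfpi, an inhibitor of the clotting cascade made by endothelium, fell from 14.4 ± 3.13 to 9.47 ± 1.68 CPM (−0.57, SE 0.10, adjusted p = 0.0387). Ddo fell from 9.21 ± 1.52 to 5.86 ± 0.847 CPM (−0.60, SE 0.11, adjusted p = 0.0387). These were the 3 genes called of 19912 tested, with 1448 at an unadjusted p under 0.05. DESeq2 called 20. Endothelial and mural markers lay below 0 in 21 of 21 members (median −0.40), and 15 were lower when adjusted over the list alone, 0 over all genes (adjusted p = 0.324 with an estimated correlation). Their mean log2 CPM was 6.06 ± 0.304 in HET and 6.44 ± 0.287 in WT (SD, n = 9 and 12). Of the 5 blood markers tested, 2 were lower adjusted over the list alone (median −0.21, adjusted p = 0.324 with an estimated correlation). Oxidative phosphorylation genes (72 of 80 above 0, median 0.10), dendritic and synaptic RNAs (17 of 20, median 0.09), presynaptic genes (43 of 53, median 0.06), microglial markers (15 of 16 below 0, median −0.12), meningeal genes (16 of 19 below 0, median −0.13) and myelin genes (19 of 20 below 0, median −0.07) had 0 members passing adjusted over the list alone and each had an adjusted p = 0.749 with an estimated correlation. Wnt pathway genes had a median of −0.05 (adjusted p = 0.691 with an estimated correlation).

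The 3 nuclear calls depended on single libraries. None remained without HET female replicate 4 or 5, HET male replicate 3 or 4, or WT female replicate 1 or 3, and 1 was called without HET female replicate 1 or 3, HET male replicate 1 or 2, WT female replicate 2, or WT male replicate 4, 6 or 7. The library labelled WT male replicate 7 had 547 CPM of Xist and 0 of the Y-linked Ddx3y, and the library labelled HET female replicate 4 had 0.428 CPM of Xist and 0 of Ddx3y. Without both, edgeR called 0 genes (1883 at an unadjusted p under 0.05).

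The synaptic fraction asks the same of RNA at synapses. In the libraries as deposited, edgeR called 0 of 17178 genes, with 1877 at an unadjusted p under 0.05 (1327 higher and 550 lower), while DESeq2 called 31 and voom with sample weights 586. The WT males of replicates 1 and 2 held 857 and 1221 CPM of Malat1, a nuclear RNA, against 18.2 to 184 CPM in the other 16 libraries, and their endothelial lists averaged 4.65 and 4.49 log2 CPM against 1.85 to 2.65. Left out after these values were seen, they gave way to 101 higher and 82 lower genes of 16862. Chd8 fell most clearly, followed in the direction of germline cortex by Rec8 (−0.91, SE 0.22, adjusted p = 0.0429), Dsn1 (−0.81, SE 0.18, adjusted p = 0.0344), Ddo (−0.70, SE 0.16, adjusted p = 0.0344) and Usp11 (−0.36, SE 0.0706, adjusted p = 0.0246). Further lower genes were the mitochondrial carrier genes Sfxn2 (−1.07, SE 0.21) and Slc25a34 (−0.70, SE 0.14), the metallothionein gene Mt2 (−1.04, SE 0.22), Tnnt2 (−0.76, SE 0.17) and Pstpip2 (−0.72, SE 0.17), with adjusted p of 0.0246 to 0.0428. The parathyroid hormone receptor gene Pth2r rose from 1.81 ± 0.66 to 2.97 ± 0.48 CPM (SD, n = 9 and 7; 0.94, SE 0.19, adjusted p = 0.031). The nicotinic receptor gene Chrnb3 (0.76, SE 0.17), Srpx2 (0.70, SE 0.15), Cyp2s1 (0.58, SE 0.14), Lrrc32 (0.56, SE 0.13), Abi3bp (0.53, SE 0.11) and Mansc1 (0.53, SE 0.12) also rose, with adjusted p of 0.0336 to 0.0439. Pcdha6 had 0.76, but 14 genes overlap it on its own strand, so its reads cannot be assigned with certainty.

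Ion channel and ribosomal protein genes made up the largest groups in the synaptic fraction without these libraries. Of 52 voltage-gated ion channel genes, 48 lay above 0 (median 0.25), 6 rose over all genes and 30 adjusted over the list alone (adjusted p = 0.319 with an estimated correlation). Examples were the sodium channel genes Scn1a (0.53, SE 0.12) and Scn8a (0.39, SE 0.08) and the fast potassium channel genes Kcnc1 (0.35, SE 0.07) and Kcnc2 (0.31, SE 0.07). Of 85 cytosolic ribosomal protein genes, 84 lay below 0 (median −0.28), 14 fell over all genes and 71 adjusted over the list alone (adjusted p = 0.319 with an estimated correlation), among them Rps2 (−0.41, SE 0.08) and Rpl23a (−0.45, SE 0.08). Both have overlapping genes and processed copies that could share reads. Of 22 inhibitory synapse genes 13 rose adjusted over the list alone and 1 over all genes, Gabbr2 (0.37, SE 0.09), and of 65 protocadherin genes 25 rose adjusted over the list alone and 5 over all genes, among them Pcdhb18 (0.51, SE 0.11); each list had an adjusted p = 0.319 with an estimated correlation. GABAergic interneuron markers had 4 of 24 higher adjusted over the list alone, with the vesicular GABA transporter gene Slc32a1 at 0.32 (SE 0.07). Pan-excitatory markers had 5 of 14, with the vesicular glutamate transporter gene Slc17a6 at 0.37 (SE 0.09), and neuropeptides had 9 of 24, all 3 lists with an adjusted p = 0.319 with an estimated correlation. In the presynaptic list 7 of 53 rose adjusted over the list alone, with Syt2 at 0.44 (SE 0.08) and Sv2c at 0.40 (SE 0.09; list adjusted p = 0.428 with an estimated correlation). The nuclear-retained list had a median of −0.47, and 2 of 16 fell adjusted over the list alone, with Rian at −0.33 (SE 0.07; list adjusted p = 0.369 with an estimated correlation). HET and WT libraries may thus differ in nuclear share, and no fit with this list as a covariate was run for this fraction. The list differences given here, the calls of this fraction and its Chd8 difference therefore cannot be assigned to genotype alone. Mitochondrially encoded RNAs had 2 of 19 lower adjusted over the list alone, with the tRNA mt-Tp at −0.51 (SE 0.10; list adjusted p = 0.447 with an estimated correlation). Camera called 17 of 35 lists in this fit, and fry called 2.

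The 183 synaptic calls were unstable. Genotype without covariates called 0 in edgeR (2131 at an unadjusted p under 0.05), sex without a batch term called 7, and DESeq2 called 986. Leaving out HET female replicate 4, 3 or 2 left 1, 2 or 6 calls, WT female replicate 3, 4, 2, 5 or 1 left 6, 7, 45, 95 or 119, HET male replicate 2 or 1 or HET female replicate 1 left 12, 26 or 27, and WT male replicate 5 left 102. Without WT male replicate 6 there were 930 calls, and leaving out HET male replicate 3 also raised their number.

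**Figure D2:**
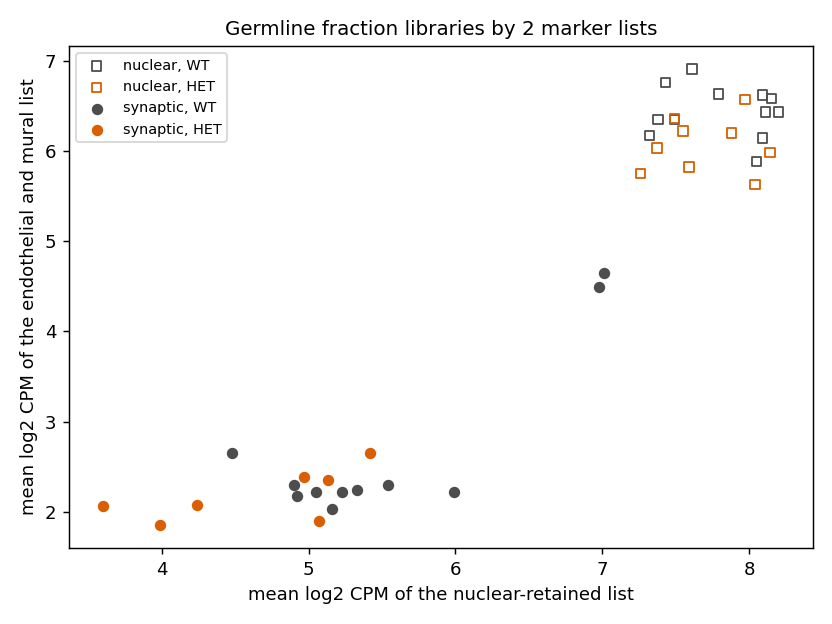
Mean log2 CPM of endothelial and mural markers (y axis) against that of nuclear-retained RNAs (x axis) in each germline nuclear (squares) and synaptic (circles) library, coloured by genotype. The 2 WT synaptic libraries at 4.65 and 4.49 on the y axis lie between the other synaptic libraries, at 1.85 to 2.65, and the nuclear libraries, at 5.63 to 6.91.

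In the cytosolic fraction 0 of 18454 genes passed in edgeR, with 587 at an unadjusted p under 0.05 and 4 called by DESeq2. Usp11 ranked first by p, at 149 ± 10.3 CPM in WT and 111 ± 10.2 CPM in HET (SD, n = 5 and 7; log2 fold change −0.46, SE 0.0828, adjusted p = 0.914, exact permutation p = 0.00126). Choroid plexus markers had a median of −0.62, and 4 of 10 were lower adjusted over the list alone (adjusted p = 0.673 with an estimated correlation). Meningeal genes (15 of 19 below 0, median −0.26) and deep-layer excitatory markers (12 of 17 below 0, median −0.12) had 0 and 1 member lower adjusted over the list alone, each with an adjusted p = 0.673 with an estimated correlation. Cytosolic ribosomal protein genes lay below 0 in 77 of 84 members (median −0.08), with 0 adjusted over the list alone (adjusted p = 0.901 with an estimated correlation). In simulated data of this size 58 of 100 genes changed by a log2 of 1 were recovered, and 3 of 100 changed by 0.5.

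Cre-positive and Cre-negative cortex, both heterozygous floxed by their titles, were compared to see the effect of losing 1 Chd8 allele in excitatory neurons. edgeR called 0 of 21798 genes, with 656 at an unadjusted p under 0.05, and DESeq2 called 4. Of 102 autism-associated genes, 94 lay below 0 (median −0.21), as did 68 of 78 chromatin remodelling genes (median −0.23), 50 of 52 voltage-gated ion channel genes (median −0.22) and 49 of 53 postsynaptic genes (median −0.18). Oxidative phosphorylation genes lay above 0 in 80 of 82 members (median 0.19). None of these 5 lists had a member passing adjusted over the list alone, and each had an adjusted p = 0.743 with an estimated correlation. Ribosomal protein genes lay above 0 in 83 of 86 members (median 0.16, 0 adjusted over the list alone, adjusted p = 0.751 with an estimated correlation). Thalamic and hypothalamic markers had a median of 0.59, with 4 of 16 higher adjusted over the list alone (adjusted p = 0.743 with an estimated correlation). The oxidative phosphorylation list averaged 5.74 to 6.81 log2 CPM in Cre-negative and 5.89 to 7.06 in Cre-positive libraries. Among Cre-negative libraries, the one with the lowest mean had 96.9 CPM of Chd8 and the one with the highest 54.2 CPM. Libraries of 1 genotype thus differed widely, and the list differences cannot be assigned to Cre. In simulated data of this size 81 of 100 genes changed by a log2 of 1 were recovered, and 12 of 100 changed by 0.5.

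In the conditional fractions HET and HOM were each compared with WT. Cre reads were present in the WT libraries of both fractions (at least 196 in nuclear and at least 68 in synaptic libraries), so these controls, unlike those of cortex, carried Cre. No gene passed in edgeR: in the nuclear fraction HET gave 938 and HOM 2453 genes at an unadjusted p under 0.05 of 21133 tested, and in the synaptic fraction HET gave 750 and HOM 836 of 17505. DESeq2 called 3, 27, 0 and 2 genes in that order. In HOM nuclei endothelial and mural markers lay below 0 in 21 of 21 members (median −0.62), 10 of them lower adjusted over the list alone, and their mean log2 CPM was 5.02 ± 0.587 against 5.62 ± 0.512 in WT (SD, n = 3 and 4; list adjusted p = 0.505 with an estimated correlation). Presynaptic genes lay above 0 in 49 of 53 members there (median 0.28, 0 adjusted over the list alone, adjusted p = 0.505 with an estimated correlation). In HET nuclei 82 of 85 ribosomal protein genes lay above 0 (median 0.19) and 19 of 21 endothelial markers below 0 (median −0.37), with 0 adjusted over the list alone and an adjusted p = 0.593 with an estimated correlation for each. The GABAergic interneuron list was higher in HET synaptic libraries, with 22 of 24 members above 0 (median 0.15, 0 adjusted over the list alone). Its adjusted p was 1.06e-06 in camera and it kept an adjusted p = 0.00509 with an estimated correlation. In a check chosen after this result was seen, leaving out any 1 library of that fraction kept the direction, with an adjusted p from 0.00596 to 0.0193. In HOM synaptic libraries 18 of 19 meningeal genes (median −0.40) and 15 of 16 nuclear-retained RNAs (median −0.35) lay below 0, with 1 and 0 adjusted over the list alone (adjusted p = 0.445 with an estimated correlation for each).

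Synaptic and nuclear WT libraries of the same animal number show what the fractionation separated. In 10 germline pairs 5808 genes were higher and 6622 lower in the synaptic fraction (edgeR with animal as a block, 18879 tested), and in 4 conditional pairs 5972 were higher and 6568 lower of 18715. The GABA receptor gene Gabrb2 (2.14, SE 0.37) and the mitochondrial gene mt-Nd5 (2.06, SE 0.18) were among the genes higher in germline synaptic libraries. Endothelial genes were far lower there, with Gkn3 at −5.48 (SE 0.55), Bmx at −5.37 (SE 0.61) and Mecom at −5.23 (SE 0.78). In conditional WT Gabrb2 was at 2.45 (SE 0.11), Pcdhgc5 at 2.46 (SE 0.10; 25 genes overlap it on its own strand, so its reads cannot be assigned with certainty), Gkn3 at −6.00 (SE 0.31) and Mall at −8.08 (SE 0.53). With nuclear and synaptic libraries scaled together by TMM, 19 of 20 dendritic and synaptic RNAs were called higher in germline and 20 of 20 in conditional synaptic libraries, as Camk2a at 1.02 (SE 0.17) and 0.81 (SE 0.11) and Shank3 at 1.07 (SE 0.10) and 0.99 (SE 0.11). The direction of small changes depends on this scaling of unlike fractions: in plain CPM, Map2 went from 1400 in nuclear to 1340 in synaptic libraries of conditional WT (log2 fold change 0.48, SE 0.14) and Lrrc7 from 67 to 65.8 in germline WT (0.40, SE 0.16). The count of 20 of 20 in conditional WT therefore holds only under this scaling. Of the nuclear-retained RNAs 13 of 16 and 12 of 16 were lower, with Malat1 at −2.88 (SE 0.39) and −3.47 (SE 0.40) and Meg3 at −2.65 (SE 0.54) and −3.02 (SE 0.26). Peg13 (1.00, SE 0.14, and 1.35, SE 0.10) and Pantr1 (0.87, SE 0.15, and 0.39, SE 0.10) were higher in both lines, and Tug1 was higher in the conditional line (0.35, SE 0.09). The conditional values of Pantr1 and Tug1 lie below that of Map2, which turned in plain CPM, so their direction rests on the scaling. Xist was lower in germline (−1.99, SE 0.66, adjusted p = 0.0175) but higher in conditional WT (2.55, SE 0.34, adjusted p = 0.000883). The germline Xist value includes the pair that disagrees in sex markers, so it mixes sex with compartment and the lines cannot be compared on it. The lists had an adjusted p = 0.281 and 0.365 (dendritic) and 0.297 and 0.365 (nuclear-retained) with an estimated correlation, and fry called 30 of 35 lists in each line. The lines shared 4804 higher and 5293 lower genes, against 1890 and 2230 for independent lists, and their log2 fold changes correlated across genes with r = 0.918, where genes are not independent replicates. Chd8 was at −0.35 (SE 0.17, adjusted p = 0.0792) in germline WT and −0.28 (SE 0.09, adjusted p = 0.0129) in conditional WT. The germline value includes both synaptic libraries of nuclear profile, and without them it was −0.60 (adjusted p = 3.3e-05). With each fraction scaled by itself the same differences were −0.89 ± 0.52 and −0.79 ± 0.18 log2 units (SD, n = 10 and 4 pairs), so their size rests on the scaling. Without the germline pair that disagrees in sex markers 5623 genes were higher and 6326 lower, with Chd8 at −0.34 (SE 0.182, adjusted p = 0.12). Its germline value passed without the animal of WT male replicate 1 (−0.47, adjusted p = 0.00894) or 2 (−0.45, adjusted p = 0.0165), while the conditional value no longer passed without the animal of WT male replicate 1 (−0.24, adjusted p = 0.0749), WT male replicate 2 (−0.26, adjusted p = 0.0559) or WT female replicate 2 (−0.24, adjusted p = 0.0763).

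Whether genotype acts differently in the compartments was tested on pairs of libraries with the same animal number. In 1 WT pair the libraries disagree in sex, with Xist and Ddx3y at 547 and 0 CPM in the nuclear and 2.61 and 34.6 CPM in the synaptic library. With each fraction scaled by itself, Chd8 in synaptic minus nuclear libraries was −1.78 ± 0.17 log2 units in HET and −0.89 ± 0.52 in WT (SD, n = 5 and 10, exact permutation p = 0.00333), a difference of −0.89. Without the animals of both libraries with a nuclear profile, the difference was −0.69 (n = 5 and 8, exact permutation p = 0.00155), and without the pair that disagrees in sex it was −0.90 (n = 5 and 9, exact permutation p = 0.0035). These tests ignore batch and any difference in nuclear share between HET and WT synaptic libraries. The paired HET males share no batch group with paired WT males. Within sex and batch group the difference was −0.41 (n = 2 and 5), with an exact permutation p of 0.0833, the smallest that 12 arrangements allow. Across genes the interaction called 0 of 21515 genes in the germline line, in edgeR and in DESeq2, with 1540 at an unadjusted p under 0.05 and Chd8 at −0.95 (SE 0.25, adjusted p = 0.59). In the conditional line the interaction, here and below, is that of HOM against WT (n = 3 and 4 pairs). It called 0 of 21577 in either tool, with 1040 at an unadjusted p under 0.05, and Chd8 was at 0.02 (SE 0.18, adjusted p = 0.999). For HET against WT edgeR called 0, with 623 at an unadjusted p under 0.05 and Chd8 at −0.10 (SE 0.158). Per pair the HET difference of Chd8 was −0.12 (n = 5 and 4, exact permutation p = 0.484). In the self-test the germline interaction recovered 5 of 100 genes changed by a log2 of 1 and 65 of 100 changed by 2, so smaller differences were mostly not detectable.

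Genes called in germline cortex were followed into the other data sets, which were taken to come from other animals. The labels do not state this, and an animal number recurs for a WT male in cortex and a HET male in cytosol. In the nuclear fraction 52 of the 55 genes tested had the direction of cortex, 29 of them at an unadjusted p under 0.05, and none was opposite at that level. In the synaptic fraction the count was 55 of 56 (54 without the libraries of nuclear profile) and in the cytosolic fraction 52 of 56. Dsn1 was at −0.58 (SE 0.122) in nuclei and −0.42 (SE 0.22) in cytosol, Abca8a at −0.53 (SE 0.122) and −0.31 (SE 0.222), and Crlf2 at 0.26 (SE 0.103) and 0.39 (SE 0.116). As sets, the genes higher and lower in cortex moved the same way in nuclei (camera adjusted p = 0.00127 and 4.58e-05 with an estimated correlation) and at synapses (0.00756 and 0.00537 with an estimated correlation, 0.00288 and 2.12e-05 without both libraries). The synaptic set tests do not stand for genotype by themselves, because 3 of 30 splits of these libraries within sex and batch group, the real one included, put as many cortex genes in the direction of cortex, with or without both libraries. In cytosol the lower set moved the same way (adjusted p = 0.00127 with an estimated correlation) and the higher set had an adjusted p = 0.0626 with an estimated correlation. In conditional cortex 45 of 56 genes had the direction of germline cortex, and the higher set (adjusted p = 0.0315 with an estimated correlation) but not the lower set (0.0626) passed. In conditional HOM the counts were 49 in nuclei and 47 at synapses, and in HET 34 and 30, with adjusted p of 0.125 to 0.992 with an estimated correlation. Over all genes the log2 fold changes of cortex correlated with those of conditional cortex at r = 0.345 (permutation p = 0.01, 0.09 after Benjamini-Hochberg adjustment over 9 correlations) and with those of HOM nuclei at r = 0.376 (permutation p = 0.03, adjusted 0.135). The other 7 correlations, across genes that are not independent replicates, ranged from 0.032 to 0.418, with permutation p of 0.07 to 0.92.

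**Figure D3:**
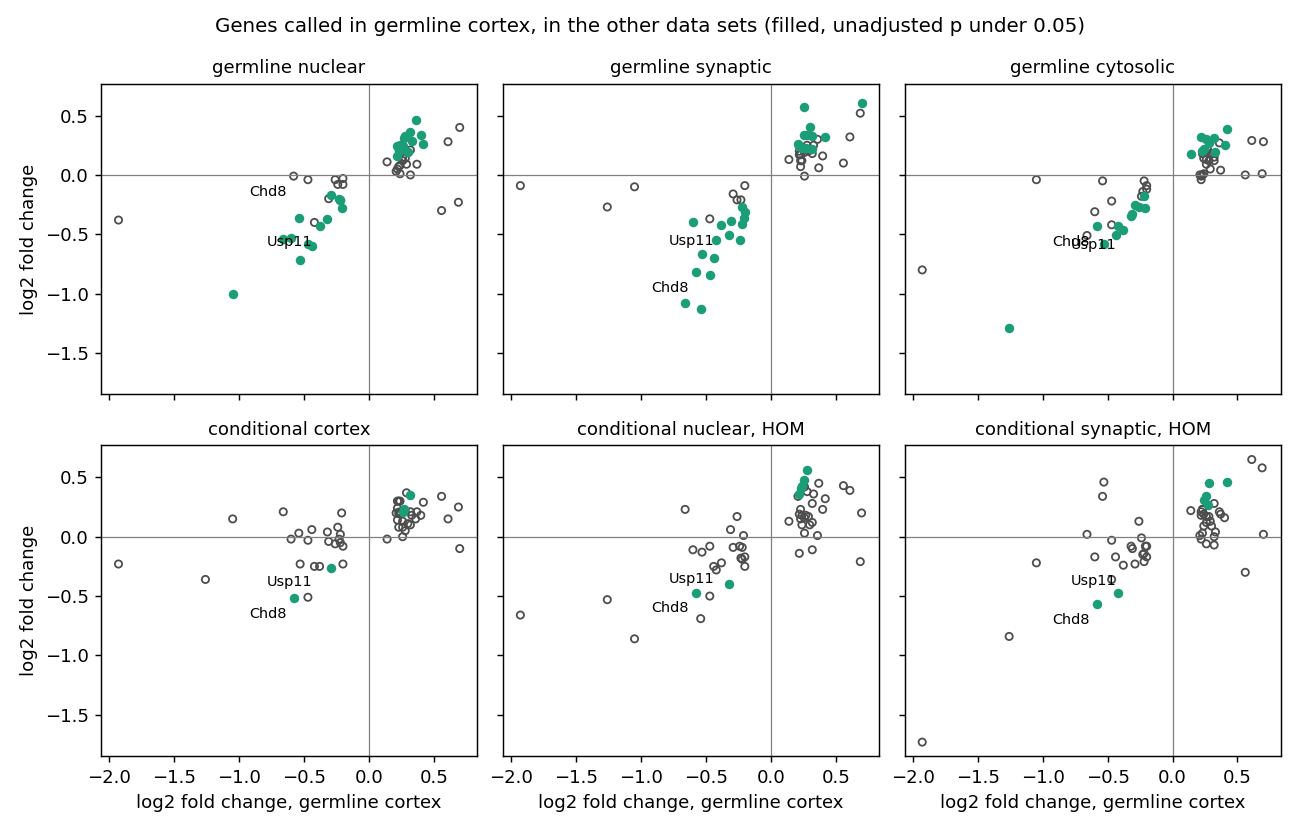
Log2 fold change of the 56 genes called in germline cortex (x axis, HET against WT) and in 6 other comparisons (y axis, mutant or Cre against control), 1 point per gene and filled where the unadjusted p in the other comparison is under 0.05. In the germline nuclear fraction 52 of 55 points share the sign of cortex while Chd8 lies at −0.01, and in conditional cortex 45 of 56 share it.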

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

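Chosen after the results were seen were the tests of genotype labels, of batch in nuclei, of loss outside the nucleus and of swapped libraries, while those of an overlapping gene, of nuclear RNA in synaptic libraries and of the 2 covariates were set before theirs.

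Chd8 in germline HET was not lower in nuclei. With batch ignored, the genotype effect differed between synaptic and nuclear libraries by −0.89 log2 units (5 HET and 10 WT pairs, of which 1 WT pair disagrees in sex markers; exact permutation p = 0.00333). Without the WT animals of both synaptic libraries with a nuclear profile it was −0.69 (n = 5 and 8, exact permutation p = 0.00155). Over all genes the interaction of Chd8 did not pass in edgeR (adjusted p = 0.59). Nuclear genotype labels unrelated to genotype are argued against, since 1 of 100 splits of these libraries, the real one, put as many as 52 cortex genes in the direction of cortex, and no single library hid a lower level (−0.04 to 0.01 with each left out). Batch differences that hide a lower level in nuclei are argued against by −0.07 (SE 0.0697) with 6 batch levels, where −0.29 would be 50% of the change in cortex. Reads of a gene on the other strand cannot be told apart, because 1 annotated gene, Gm26590, overlaps an exon of Chd8, although its reads came to 0.12% of those of Chd8. Whether RNA of the mutant allele may be lost outside the nucleus cannot be told apart either, since within sex and batch group the difference was −0.41, only 12 arrangements exist (exact permutation p = 0.0833), and no measurement here separates the alleles.

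The 2 synaptic WT male libraries of replicates 1 and 2 had a nuclear profile, with nuclear-retained lists at 7.33 (mean log2 CPM, nuclear and synaptic libraries scaled together) against at most 6.31 in the other synaptic libraries. A swap with the nuclear library of the same animal is argued against, since those nuclear libraries were nuclear as well, with the lower of both at 7.11. As mixtures of synaptic and own nuclear RNA they would hold nuclear shares of 74.9% and 99%, but such mixtures miss the endothelial list by −1.47 and −1.46 log2 units, which argues against plain carry-over of nuclear RNA as the whole cause. Their Chd8 of 144 and 148 CPM also lay above the 117 ± 10.7 CPM of WT nuclei (SD, n = 12). A fraction of another composition or libraries of another sample stay open, and no biological explanation was tested.

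For the genes called in germline cortex, a different share of nuclear RNA between libraries is argued against as the whole cause, since 56 of 56 kept at least 50% of their log2 fold change with the nuclear-retained list as a covariate (127 genes were then called, 44 of them shared). Choroid plexus carried over in dissection is argued against for most of them, since 55 of 56 kept as much with the choroid plexus list as a covariate. Aqp1 is the exception: its log2 fold change went from −1.93 (SE 0.37) to −0.92 (SE 0.33, edgeR adjusted p = 0.215). With that covariate 38 genes were called and 26 of the 56 remained, so single calls depend on it even where fold changes were kept. A response to the Chd8 genotype stays open as a hypothesis beside the structure of the samples described under the other observations.

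Of 60 tests for a single distant library (4 measures in 15 groups of 4 to 10 libraries), 3 found one, and 3 are expected by chance. The cytosolic library of HET female replicate 5 had the lowest total of its group, 36.09 M gene counts against 52.07 M for the next. In germline cortex HET female replicate 9 had the lowest mean of the nuclear-retained list, 4.98 against 6.04 for the next, and HET female replicate 8 had the highest mean of the choroid plexus list, 1.13 against 0.44. Cre reads, outside the gene counts, numbered at least 460 in each of the 6 conditional cortex libraries with Cre and 0 in the 8 without.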

How the results depend on the processing

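Fits without doubted libraries were chosen after seeing the data, and all others were set before. Of 200 values under settings chosen beforehand, 159 stayed as in the main fit, as did 26 of 39 under added ones. Counts had to stay within 1.5 times the main count, and correlations and passing values had to keep direction and side of the threshold. Chd8 values that passed in neither fit had only to stay within their SE, whatever their sign. No passing value reversed. Of the values of single named genes 724 stayed, 170 lost and 1 gained the threshold, the losses mostly in the synaptic fraction without 2 libraries (104) and in germline cortex (47). The cause of the changes below was not tested, except that fewer samples enter single batches and reduced sets.

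DESeq2 called 101 genes in germline cortex, 4 in conditional cortex, 20 in the germline nuclear, 31 in the synaptic and 4 in the cytosolic fraction, 3 and 27 for HET and HOM conditional nuclei and 2 for HOM synapses, with Chd8 at −0.82 (adjusted p = 0.0303) in the synaptic and −0.43 (adjusted p = 0.0306) in the cytosolic fraction. Without the filter on low counts the calls were 21 in germline cortex, 284 nuclear, 276 synaptic, 1 cytosolic, 64 and 346 for HET and HOM conditional nuclei, 20 and 97 for HET and HOM synapses and 8 for the conditional interaction, with Chd8 at −0.79 (adjusted p = 1.29e-05) in the germline synaptic fraction and −0.56 (adjusted p = 0.000212) in HOM synapses. Voom with sample weights called 586 synaptic genes and 1 for the germline interaction, with Chd8 at −0.70 (adjusted p = 0.000102) in the synaptic fraction and −0.54 (adjusted p = 1.09e-05) between compartments of WT. In single batches germline cortex gave 0 and 1 calls, with Chd8 at −0.57 (adjusted p = 0.999) in the batch with 0. In the nuclear fraction genotype alone, sex alone, 6 batch levels (Chd8 −0.07) and the set without 2 libraries of contrary sex markers each called 0 in edgeR (1260, 1247, 781 and 1883 genes at an unadjusted p under 0.05). With 6 batch levels Chd8 was at −0.40 (adjusted p = 0.421) in the synaptic fraction.

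Replicate numbers were not taken to pair the libraries. Of 59 pairs of the same number, 23 had deviations correlated above 0.1, from −0.436 to 0.705. In germline cortex such pairs had a mean correlation of 0.167, against −0.018 for pairs of different number. In the other experiments the mean for pairs of the same number lay from −0.053 to 0.08. With the replicate block germline cortex called 35 genes, the nuclear fraction 0 (1393 at an unadjusted p under 0.05) and the cytosolic fraction 217, with cytosolic Chd8 at −0.52 (adjusted p = 0.0281). The block changed no other count of calls except that of the reduced synaptic set, and leaving out the animal block between compartments changed none by over 1.5 times.

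Without the 2 synaptic libraries of nuclear profile the synaptic calls rose from 0 to 183, with Chd8 at −0.67 (adjusted p = 6.26e-05) and at −0.60 (adjusted p = 3.3e-05) between compartments of WT. On that set DESeq2 called 986 genes (681 higher and 305 lower), no filter 1200, voom 688, 6 batch levels 482, sex without batch 7, genotype alone 0 (Chd8 −0.65, adjusted p = 0.0725) and the replicate block 0 (Chd8 −0.64, adjusted p = 0.519). Over the 9 genotype comparisons and 2 interactions, gene lists held in 1 case with an estimated correlation and in 3 with fry (2 in the germline synaptic fraction and 1 in HET synapses). The correlation of cortex with cytosolic fold changes was −0.004 by Spearman (permutation p = 0.98), and that with HOM nuclei was 0.52 (permutation p = 0.06) for genes of a log2 CPM of at least 3.

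Leaving out 1 library at a time gave 29 to 75 calls in germline cortex, 0 to 4 in the nuclear fraction, 1 to 930 in the reduced synaptic set, 11091 to 13166 between compartments of germline WT and 11208 to 12675 of conditional WT, and 0 to 0 elsewhere. Chd8 then lay from −0.60 to −0.55 in germline cortex, 0.00 to 0.11 for the sex interaction, −0.63 to −0.43 in conditional cortex, −0.04 to 0.01 in nuclei, −1.03 to −0.72 at synapses (−0.71 to −0.61 in the reduced set) and −0.49 to −0.37 in cytosol. It lay from −0.10 to 0.06 and −0.65 to −0.20 in HET and HOM conditional nuclei, −0.32 to −0.13 and −0.69 to −0.45 at HET and HOM synapses, −0.47 to −0.27 and −0.35 to −0.24 between compartments of germline and conditional WT, and −1.02 to −0.83 and −0.21 to 0.11 for the germline and conditional interactions. Between compartments of conditional WT it was at −0.26 without male replicate 2 (adjusted p = 0.0559). Depth was at least 19 M gene counts in every library, and counting limits named genes of low level, as Mall at 0.0123 and Gkn3 at 0.0881 CPM in conditional synaptic WT and Aqp1 at 0.366 CPM in germline cortex HET.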

Other observations

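The tests of Usp11 outside the named-gene rule, also within sex and batch group, and the count of genes at an unadjusted p for the splits of comparisons without calls, were chosen after the results were seen.

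Usp11, on the plus strand of chromosome X from 20703906 to 20720539 in GRCm38 with no annotated antisense gene, was lower in HET than in WT in all 4 germline data sets, but over all genes it passed only in cortex among the data sets as deposited (edgeR adjusted p = 0.206 in nuclei, 0.316 in the synaptic fraction as deposited and 0.914 in cytosol). Beside cortex it was at 105 ± 23.3 CPM in WT and 77.0 ± 15.4 CPM in HET nuclei (SD, n = 12 and 9, exact permutation p = 0.00608), at 118 ± 35.2 and 74.6 ± 9.40 CPM in the synaptic fraction (SD, n = 11 and 7, exact permutation p = 0.000754) and at 149 ± 10.3 and 111 ± 10.2 CPM in cytosol (SD, n = 5 and 7, exact permutation p = 0.00126). After Benjamini-Hochberg adjustment over its 13 tests these values were 0.0158, 0.0049 and 0.00546, for a gene picked after its values were seen. Within sex and batch group the difference was −0.42 in nuclei (exact permutation p = 0.00417) and −0.43 in the synaptic fraction (exact permutation p = 0.0333, the smallest possible). Unlike Chd8, Usp11 had nearly the same log2 fold change in nuclei (−0.43, SE 0.0899) and in cortex (−0.38, SE 0.0494), and its interaction with the compartment was −0.09 (SE 0.194, edgeR adjusted p = 0.887). In the conditional line it was at −0.25 (SE 0.156) in Cre-positive cortex, −0.22 (SE 0.18) and −0.24 (SE 0.204) in HOM nuclei and synapses, and 0.03 (SE 0.148) and −0.07 (SE 0.202) in HET, with edgeR adjusted p of 0.605 to 0.997.

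Genes called in both germline cortex and the synaptic fraction without 2 libraries were mostly lower ones. The comparisons shared 9 lower genes, against 0.121 for independent lists, and 2 higher genes, against 0.196. Protocadherin genes lay above 0 in 62 of 65 members in that synaptic set (median 0.26), while in cytosol 48 of 65 lay below 0 (median −0.15, adjusted p = 0.901 with an estimated correlation) and in conditional cortex 55 of 66 did (median −0.19, adjusted p = 0.743 with an estimated correlation). The difference between these data sets was not tested.

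Other splits of the same libraries were compared with the real ones. In germline cortex 2 of 100 splits, the real one included, called 56 genes or more, a share under 0.05 without adjustment for the number of comparisons. The highest other split called 1473, which points to a structure of the samples that sex and batch do not hold. The mean log2 CPM of the striatum list ranged from 2.16 to 5.04 in these libraries (2.90 ± 0.82 in HET and 3.14 ± 1.00 in WT, SD). No fit used this list as a covariate, so its part in that structure was not tested. In the germline nuclear fraction 3 of 100 splits gave the 3 calls of the real one or more (highest other 7), but those calls depended on single libraries. For synaptic libraries the real split gave the most genes, as deposited (1 of 30, 1877 genes at an unadjusted p under 0.05 against 1393) and without 2 libraries (1 of 30, 183 calls against 5). Only 3 HET and 5 WT female libraries could change labels in these 30 splits, while every male kept its own. As 1 of 30 is also the smallest possible share, the synaptic splits cannot exclude chance or batch for the whole fraction. Between compartments of germline WT the real split was the highest (1 of 100, 12430 calls against 7063), and in conditional WT the 8 splits are too few (1 of 8, 12540 calls against 0). Chance cannot be excluded for the sex interaction (80 of 100 splits, 261 genes at an unadjusted p under 0.05 against 3928), conditional cortex (32 of 100, 656 against 9385), the cytosolic fraction (43 of 100, 587 against 6166), HET and HOM nuclei (29 and 6 of 100, 938 against 5777 and 2453 against 5341), HET and HOM synapses (53 and 41 of 100, 750 against 2572 and 836 against 2613) and the germline and conditional interactions (7 and 14 of 50, 1540 against 5422 and 1040 against 3854). In conditional cortex and the cytosolic fraction other splits reached 6491 and 2955 calls in edgeR where the real split had 0, and these too point to a structure of the samples.

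For the 56 cortex genes, the real genotypes gave 52 of 55 in the direction of cortex in nuclei, where the other splits reached at most 51 (median 37). In cytosol they gave 52 against at most 53, in conditional cortex 45 against at most 47, and in the synaptic fraction 55 against at most 55. The batch of the synaptic fraction leaves only 30 splits, and the other splits had a median of 51, so the synaptic count says little by itself.

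Conditional HET male replicate 1, labelled as carrying Cre, had 0 Cre reads in its nuclear and in its synaptic library, where all other conditional fraction libraries had at least 52. Without it and the animal labelled HET in one fraction and HOM in the other, Chd8 in HET against WT was at −0.09 in nuclei (n = 4 and 4, exact permutation p = 0.343) and −0.30 at synapses (n = 4 and 4, exact permutation p = 0.0571).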
